A study of Mus musculus with 93 samples.

How the data were processed

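RNA of mouse granulosa and oocyte samples was measured by Smart-seq2 in 93 samples, 42 of granulosa cells and 51 of oocytes, from wild type and Esr2 knockout mice of 3 ages. The protocol text also mentions miRNA sequencing, which was not analysed here. Each combination of cell type and age came as 1 table of counts and 1 table of normalised values. Per the labels, the authors used STAR, Partek and DESeq2, without versions, and the mm10 genome, and the gene annotation is not stated.

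The deposited count tables hold expected counts, that is estimated read counts per gene that the authors did not normalise. Many of these values are not whole numbers, and they were rounded before testing. The deposited normalised tables hold signal values: the authors rounded each count and divided it by 1 size factor per library, which was checked on the values. They were used only in 1 alternative test. Samples were assigned to the 12 groups by their titles. In the 7 week oocyte knockout group 1 column had no sample label of its own. Its name joins the numbers 4 and 5. Number 5 has a column of its own and number 4 has none, so it may be sample 4. Wild type 4 would then have a knockout library of the same number. Whether the column is a pool, a rerun or a separate sample is not known, and the 12 knockout libraries of that group may not be 12 separate samples. It was kept in that group as an unnumbered library and left out of the fits with a replicate block. No library was left out of the main comparisons, and no pair of libraries held identical values.

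Knockout was compared with wild type within each cell type and age. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16, with robust dispersion, in R 4.3.3. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were counted. For each cell type the 3 tables were then joined by gene and 1 model with a mean per group was fitted. Its contrasts tested whether the knockout effect differed between ages, and how wild type libraries differed between ages. Fold changes are log2 ratios of knockout over wild type, or of the later over the earlier age, with standard errors (SE) from the fit. Means in CPM, counts scaled to the library's total after TMM for genes and to its total for Esr2 and marker sums, carry the standard deviation (SD) over libraries.

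The gene lists were written before the data were examined, as were the comparisons, the tests, the rule for naming genes, the first set of alternatives and the splits of the samples. There were 24 gene lists and 9 lists of cell type markers, with 5 to 51 genes per gene list and 600 genes on the gene lists in all. None of the 13 mitochondrially encoded genes could be tested. Members were counted with p adjusted over all genes and adjusted over the list alone. Lists with at least 5 tested members were tested as sets with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. Of the camera calls that the text gives for knockout against wild type, those on the luteal and immune lists in 4 week granulosa cells and on the endoplasmic reticulum chaperone list in 4 week oocytes held with an estimated correlation. Those on the steroid receptors in oocytes at each age, and on the genes near Esr2 at 4 weeks, held too but rested on Esr2. Of the contrasts, the luteal list between 4 weeks and 6 months held. Summed marker shares were compared by exact two-sided permutation tests on log2 shares, adjusted over 54 tests.

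Named genes in each knockout comparison were Esr2 and Esr1, then the 10 higher and 10 lower genes with the smallest p among those past the test with a mean of at least 5 CPM in the higher group. Predicted, clone-named, pseudogene and unnamed loci were left out. Up to 4 members with the smallest p followed for each list that is described. Genes past the test at more than 1 age were ranked by the largest of their p, up to 10. Contrasts gave the 5 higher and 5 lower genes with the smallest p, and those of wild type ages up to 4 members per described list. Named outside this rule, after their values were seen, were Prlr, Star, Cyp19a1, Col4a2 and Nid2 in granulosa cells at 4 weeks, Akr1c18 and Ptgfr there at 7 weeks, Lhcgr there at 6 months, Gdf9 in oocytes at 4 weeks and 6 months, Zp3 in oocytes at 6 months, and the transcripts abundant in granulosa cells. Coordinates are those of GRCm38 (mm10) from GENCODE vM21.

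For Esr2, a group with no counts was set to a floor of 3 counts over the group, and ratios with few counts carry 95% intervals for the ratio of 2 Poisson rates. Both cover counting error only. The sample numbers were checked for pairing by correlating the residuals of libraries with the same number. In 7 week oocytes all 4 shared numbers gave a correlation above 0.1 (0.543, 0.118, 0.154 and 0.243), so the numbers were taken as pairs there. The labels name no pairs, so this is an assumption. Values of the fit with the replicate block are given where they changed a call or a count. Recovery of known changes was tested on simulated data of the same group sizes.

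Alternatives planned beforehand were DESeq2's size factors or upper quartile factors, no count filter or a mean of at least 10 CPM, dispersion without the robust option, the DESeq2 test (1.42.0), limma voom with sample quality weights, limma on the authors' normalised values, low-depth libraries left out, the other cell type's markers as a covariate, the replicate block, and each library left out in turn (for contrasts between ages only those of groups of 4 or 5 libraries). Chosen after seeing the data were leaving out the 3 shallowest 7 week granulosa libraries, 1 granulosa library with oocyte markers, or 2 outlying oocyte libraries. Added as well were erythroid and immune shares as covariates, Esr2 left out of the lists, and loess trends (span 0.5) on transcript length, or length and GC content, removed from each library. The result for 1 gene in granulosa cells at 4 weeks is not reported here. Tables were merged with pandas 2.3.3 and figures drawn with matplotlib 3.10.9 in Python 3.11.15.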

Results

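Granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle, and oocytes were profiled by Smart-seq2, a full-length cDNA method for very small RNA inputs. The mice were wild type or lacked a working Esr2 gene, which encodes estrogen receptor beta, and were 4 weeks, 7 weeks or 6 months old. The 93 samples fell into 12 groups by cell type, age and genotype. Granulosa samples numbered 7 wild type and 7 knockout at 4 weeks, 5 and 5 at 7 weeks, and 12 and 6 at 6 months. Oocyte samples numbered 12 and 7 at 4 weeks, 5 and 12 at 7 weeks, and 11 and 4 at 6 months. The column of 1 knockout oocyte library at 7 weeks joins 2 sample numbers in its name, so the 12 there are not known to be separate samples. The labels name no animals, litters or library batches, and no number of cells per library, so each library was treated as a replicate. All p-values therefore measure only the spread between libraries, which may in part be technical.

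Total estimated counts per granulosa library ran from 1413787 to 6469427 in 4 week wild type and from 2814193 to 4085477 in 4 week knockout samples. At 7 weeks they ran from 702731 to 5158828 and from 714209 to 6377094, and at 6 months from 826031 to 5083133 and from 1486394 to 5130428. Oocyte libraries held 2415447 to 6485263 counts in wild type and 3992040 to 5690568 in knockout at 4 weeks. The oocyte ranges were 2278359 to 5209452 and 1814959 to 6134435 at 7 weeks, and 2211699 to 7172712 and 4119875 to 7751961 at 6 months. Among granulosa libraries, genes with at least 1 count numbered from 13969 (6 month wild type) to 18734 (4 week knockout), and among oocyte libraries from 12751 (4 week knockout) to 15631 (6 month wild type). The fixed granulosa markers took a median of 1.15% of the counts in granulosa libraries and 0.103% in oocyte libraries. Oocyte markers, such as the zona pellucida genes, took a median of 5.07% in oocyte libraries, and between 0.00384% and 0.121% in granulosa libraries. Every library thus carried the markers of its labelled cell type.

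Esr2 was present in every wild type library and nearly absent from every knockout library. In wild type granulosa libraries its mean was 30.3 ± 9.69 CPM (counts scaled to library size; SD, n = 7) at 4 weeks, 25.8 ± 6.74 (SD, n = 5) at 7 weeks and 11.5 ± 4.64 (SD, n = 12) at 6 months. Wild type oocytes held more, with 88.0 ± 17.4 (SD, n = 12), 69.8 ± 11.9 (SD, n = 5) and 73.2 ± 19.9 (SD, n = 11) CPM. No knockout granulosa library had an Esr2 count. With counts pooled over the libraries of each group and a floor of 3 counts for the knockout group, wild type Esr2 was at least 256.5-fold higher at 4 weeks, at least 129.1-fold at 7 weeks and at least 66.35-fold at 6 months. Knockout oocytes had 1 count at 4 weeks, for a ratio of 3137 (95% counting interval 562.7 to 123900). They had 4 counts in 2 of 12 libraries at 7 weeks, for a ratio of 973.3 (379.3 to 3577), and 0 counts at 6 months, where wild type was at least 586.4-fold higher. These floors and intervals cover counting error only. Esr2 lies on chromosome 12 from 76120419 to 76177259 in the GRCm38 assembly (mm10). Of the fixed list of genes on its stretch of chromosome, 18 to 21 were tested in granulosa and 17 in oocyte libraries. None but Esr2 itself passed at 4 or 7 weeks, or in oocytes at 6 months. In 6 month granulosa libraries Hspa2 was higher in knockout (log2 0.82 ± 0.24 SE, adjusted p = 0.0278) and Plekhg3 lower (-0.83 ± 0.27, adjusted p = 0.0428).

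**Figure D1:**
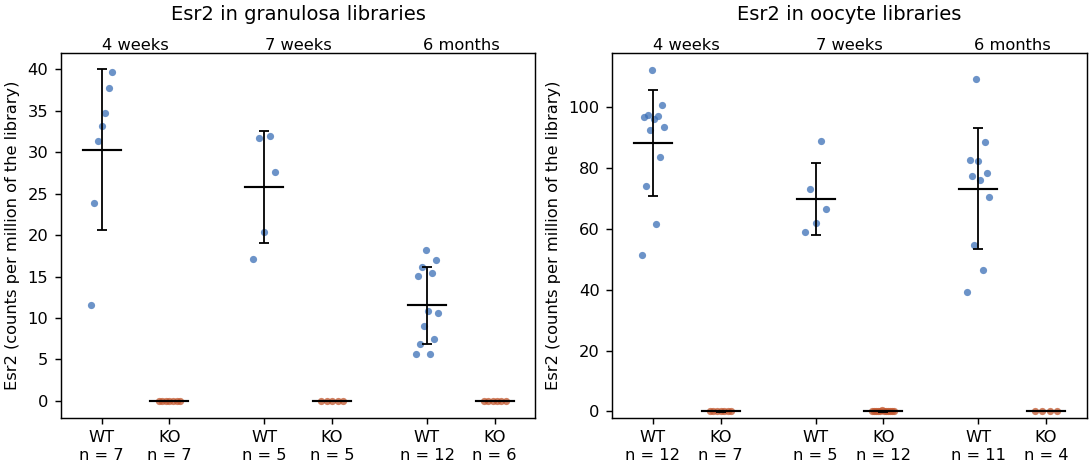
Esr2 in CPM of each library, for granulosa libraries (left) and oocyte libraries (right) by age and genotype (WT wild type, KO knockout). Points are libraries, black lines means and bars SD. Wild type means ran from 11.5 to 30.3 in granulosa and from 69.8 to 88.0 in oocyte libraries, while knockout points lie at or next to 0.

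The 4 week granulosa comparison asks what the loss of estrogen receptor beta changes in granulosa cells of young females. Lhcgr, the luteinizing hormone receptor that lets a follicle respond to the ovulatory signal, was low in knockout cells: 2.34 ± 0.844 CPM (SD, n = 7) against 45.2 ± 29.7 (SD, n = 7) in wild type. Its log2 fold change, knockout over wild type, was -4.24 ± 0.42 (SE). Akr1c18, which inactivates progesterone, fell from 1515 ± 584.7 to 264.6 ± 138.9 CPM (SD, n = 7 each; log2 -2.52 ± 0.31). Cyp11a1, the enzyme that opens steroid synthesis by cutting the cholesterol side chain, fell from 5230 ± 2897 to 1747 ± 660.2 CPM (log2 -1.58 ± 0.35). Thbs4, a matrix thrombospondin, fell from 273.9 ± 109.2 to 22.5 ± 11.5 CPM (log2 -3.60 ± 0.37). In the other direction Grb14, an adaptor that damps insulin receptor signalling, rose from 71.1 ± 25.4 to 295 ± 64.4 CPM (log2 2.05 ± 0.24), and Clu, the secreted chaperone clusterin, from 878.7 ± 569.1 to 5241 ± 1592 CPM (log2 2.58 ± 0.38). Each of these genes moved in its direction in 7 of 7 knockout libraries against the wild type median.

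Among the other genes with the smallest p at 4 weeks, those lower in knockout included Entpd1 (-2.56 ± 0.29) and Nt5e (-3.10 ± 0.35), the cell surface enzymes that turn extracellular ATP into adenosine. The collagen genes Col6a3 (-3.41 ± 0.33) and Col18a1 (-1.87 ± 0.19), the lipid kinase gene Pik3c2g (-2.82 ± 0.28), Dmbt1 (-2.78 ± 0.30) and Rusc1 (-1.81 ± 0.18) were lower as well. Genes higher in knockout included Aldh1a1 (2.72 ± 0.34), which makes retinoic acid, Ptgis (2.00 ± 0.27), the prostacyclin synthase, and Lgr6 (3.38 ± 0.50), a receptor for R-spondins. Itih5 (4.26 ± 0.56), the keratin gene Krt20 (4.43 ± 0.62), Elmo1 (2.07 ± 0.26), Slc27a3 (1.81 ± 0.27) and Pmm1 (1.61 ± 0.22) were also higher. The remaining estrogen receptor gene, Esr1, had a log2 value of 0.92 ± 0.39 and did not pass (adjusted p = 0.346).

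Luteal genes, those that mark the step from granulosa to luteal cell, fell together at 4 weeks. Of 12 measured, 6 were lower and none higher over all genes, and 7 were lower when adjusted over the list alone. Besides Lhcgr, Akr1c18 and Cyp11a1, these were the prostaglandin F receptor gene Ptgfr (-2.71 ± 0.45), the oxytocin receptor gene Oxtr (-1.93 ± 0.35) and the prolactin receptor gene Prlr (-1.16 ± 0.25; adjusted p = 0.00978). The list as a set was lower by camera (adjusted p = 2.86e-16, and adjusted p = 0.0142 with an estimated correlation). Of 15 genes of ovulation and cumulus expansion, 2 were lower over all genes and 5 when adjusted over the list alone, among them the protease gene Adamts1 (-1.12 ± 0.29). That set's camera adjusted p was 3.85e-05, and adjusted p = 0.0543 with an estimated correlation. Of 16 steroidogenesis genes, 2 were lower (Akr1c18 and Cyp11a1) over all genes and over the list alone. Their camera adjusted p was 0.0145, and adjusted p = 0.395 with an estimated correlation. Star, which carries cholesterol into mitochondria, had a value of -0.49 ± 0.32 (adjusted p = 0.744), and the aromatase gene Cyp19a1 -0.76 ± 0.49 (adjusted p = 0.72).

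**Figure D2:**
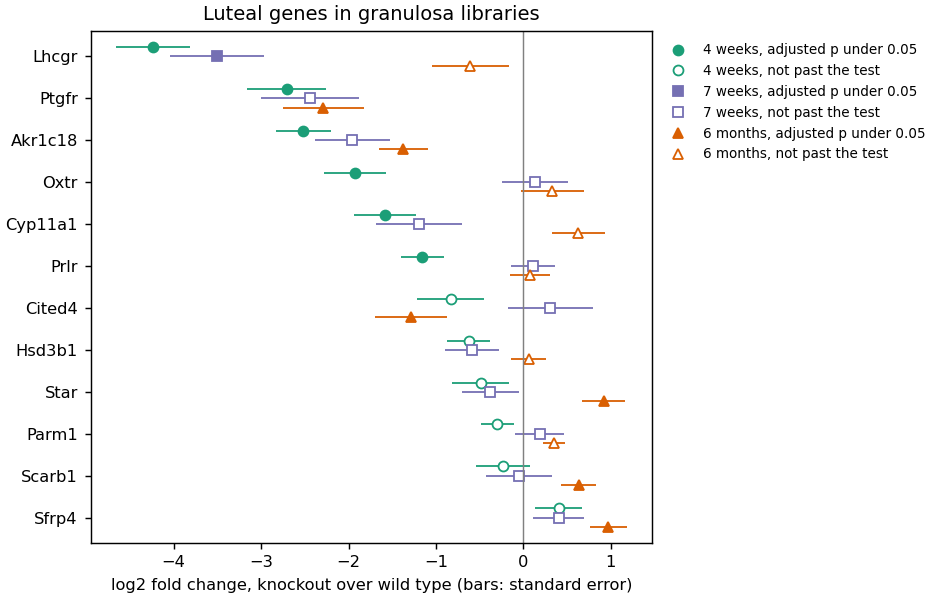
Log2 fold changes (knockout over wild type, x axis) of the 12 luteal genes in granulosa libraries at 4 weeks (circles), 7 weeks (squares) and 6 months (triangles), with standard errors as bars. Filled symbols passed an adjusted p of 0.05. Filled symbols number 6 at 4 weeks, all left of 0, and 1 at 7 weeks, Lhcgr at -3.51.

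Granulosa identity as a whole did not move one way at 4 weeks. Of 28 granulosa and FSH-responsive genes, 2 were higher and 2 lower over all genes, and 3 and 2 when adjusted over the list alone. Kitl, the ligand through which granulosa cells stimulate the oocyte's Kit receptor, was higher (1.57 ± 0.30), as was Kctd14 (1.40 ± 0.27), and the transcription factor gene Runx2 was lower (-0.99 ± 0.21). The list's camera adjusted p was 0.731. Of 28 matrix and adhesion genes, 4 were higher and 3 lower (6 and 7 adjusted over the list alone). The basement membrane genes Col4a1 (1.23 ± 0.22), Col4a2 (1.03 ± 0.26) and Nid2 (2.24 ± 0.54) were higher, and Col5a1 (-1.88 ± 0.30) and fibronectin, Fn1 (-1.64 ± 0.31), were lower. Of 33 TGF-beta family genes, 3 were higher over all genes (4 higher and 3 lower adjusted over the list alone), such as the co-receptor gene Tgfbr3 (1.31 ± 0.28) and the target gene Id3 (1.14 ± 0.25). Among 23 cholesterol synthesis genes, Fdps was lower (-0.99 ± 0.20). None of 31 cell cycle genes passed, over all genes or over the list alone; the set's camera adjusted p was 0.0137 (lower), and adjusted p = 0.498 with an estimated correlation.

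Markers of other cell types also differed with genotype at 4 weeks. Erythroid markers summed to 18.8 ± 10.8 CPM (SD, n = 7) in knockout and 291.6 ± 301.1 (SD, n = 7) in wild type libraries (exact two-sided permutation test, adjusted p = 0.0157 over 54 tests). Hemoglobin genes Hba-a1 (-3.86 ± 0.58) and Hbb-bs (-4.06 ± 0.74), the 2 erythroid markers tested, were both lower. Immune markers summed to 518.3 ± 145.9 against 1258 ± 658.8 CPM (exact permutation adjusted p = 0.0476), with 4 of 14 lower over all genes and 9 adjusted over the list alone, such as Lyz2 (-1.86 ± 0.40) and Cd52 (-1.80 ± 0.40). The immune set was lower by camera (adjusted p = 8.04e-09, and adjusted p = 0.0464 with an estimated correlation). Theca and stroma markers summed to 502.7 ± 60.7 against 1006 ± 346 CPM (exact permutation adjusted p = 0.0157), a difference carried by Apoe: the other 14 markers summed to 262.8 ± 49.6 against 289.9 ± 157.8 CPM (exact permutation p = 0.951). Markers enriched in mural granulosa cells, the layer along the follicle wall, summed to 1770 ± 588.1 against 5050 ± 2635 CPM (exact permutation adjusted p = 0.0476). The fall rests on the members that are luteal or ovulation genes as well, such as Cyp11a1 and Lhcgr. The sum of its 3 other members was higher in knockout, at 26.4 against 14.1 CPM (exact permutation p = 0.0105). Cyp19a1, among these, had a negative log2 value that did not pass. In each of these lists as a whole, 7 of 7 knockout libraries lay below the wild type median.

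**Figure D3:**
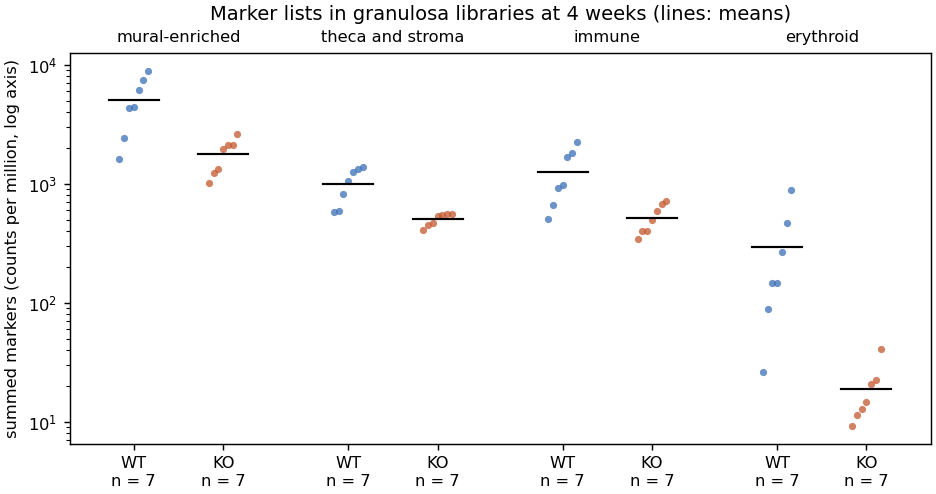
Summed CPM (log axis) of 4 marker lists in the granulosa libraries at 4 weeks, by genotype (WT wild type, KO knockout). Points are libraries and black lines means. Erythroid markers averaged 18.8 in knockout and 291.6 in wild type libraries, and mural-enriched markers 1770 and 5050.

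At 4 weeks, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 283 of 12161 genes, 119 higher and 164 lower in knockout, of which 256 differed at least 2-fold. With the erythroid share of each library as a covariate 22 genes passed, all 22 lower and all 22 among the 283, and with the immune share 90 passed, 84 of them among the 283. These shares separate the genotypes, so the covariate and the genotype overlap. DESeq2 called 559 genes, which held all 283, and limma voom 446, which held 267.

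At 7 weeks the granulosa comparison asks the same of young adults. Thbs4 was again low in knockout cells, at 14.9 ± 8.27 against 237.1 ± 42.2 CPM (SD, n = 5 each; log2 -3.92 ± 0.38), and so was Lhcgr, at 4.28 ± 2.72 against 51.1 ± 31.8 CPM (log2 -3.51 ± 0.54). Thrb, the gene of thyroid hormone receptor beta, rose from 3.35 ± 0.79 to 26.6 ± 7.37 CPM (log2 2.94 ± 0.34), and the basement membrane collagen gene Col4a1 from 227.6 ± 69.3 to 1039 ± 287.3 CPM (log2 2.19 ± 0.29). Other genes higher in knockout were the calcium pump gene Atp2b4 (2.53 ± 0.30), Grb14 (2.04 ± 0.26), the collagen crosslinking enzyme gene Loxl2 (1.78 ± 0.24), Pak3 (2.13 ± 0.29), Eya4 (2.78 ± 0.39), Lgr6 (4.07 ± 0.59), Rasgrp3 (2.83 ± 0.42) and Smoc1 (2.11 ± 0.32). Lower were the R-spondin receptor gene Lgr5 (-3.84 ± 0.62), Tspan8 (-3.52 ± 0.45), Xpnpep2 (-2.77 ± 0.45), the retinaldehyde reductase gene Dhrs3 (-1.98 ± 0.31), the keratin gene Krt18 (-1.98 ± 0.34), Dram1 (-1.82 ± 0.30) and Lin7b (-1.39 ± 0.23). Each moved in its direction in 5 of 5 knockout libraries. Esr1 had a value of 0.53 ± 0.39 (adjusted p = 0.471).

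Of 29 matrix and adhesion genes at 7 weeks, 4 were higher and none lower over all genes, and 5 higher and 1 lower when adjusted over the list alone. Besides Col4a1 and Loxl2, Col4a2 (1.80 ± 0.30) and nidogen, Nid2 (2.80 ± 0.49), were higher. The set was higher by camera (adjusted p = 0.00821), but adjusted p = 0.259 with an estimated correlation. Of 12 luteal genes, 1 (Lhcgr) was lower over all genes and 3 adjusted over the list alone. Akr1c18 (-1.96 ± 0.43, adjusted p = 0.05004) and Ptgfr (-2.44 ± 0.56, adjusted p = 0.0572) had values on the same side. The camera adjusted p of the luteal set was 0.00821, and adjusted p = 0.389 with an estimated correlation. Among 31 TGF-beta family genes Tgfbr3 was higher (2.23 ± 0.45), with 5 higher adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.528 with an estimated correlation). Among 23 cholesterol synthesis genes Fdps was lower (-1.05 ± 0.22). None of 31 cell cycle genes passed over all genes, while 1 was higher and 6 lower adjusted over the list alone; none of 19 glycolysis genes passed in either count. Camera placed both sets lower (adjusted p = 3.49e-04 each), with adjusted p = 0.374 and adjusted p = 0.528 with an estimated correlation. In the steroid receptor list the mean was -0.83 and the median 0.53, because Esr2 alone fell.

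Markers of the ovarian surface epithelium summed to 342.2 ± 122.4 CPM (SD, n = 5) in 7 week knockout and 1087 ± 530.4 (SD, n = 5) in wild type granulosa libraries (exact permutation adjusted p = 0.0476). Krt18 and Krt8 (-1.71 ± 0.30) were the 2 of 9 tested that were lower, and 3 were lower adjusted over the list alone. That set's camera adjusted p was 0.00189, and adjusted p = 0.528 with an estimated correlation. Cumulus-enriched markers, of the granulosa cells next to the oocyte, summed to 436.2 ± 112.6 against 280.8 ± 57.5 CPM (exact permutation adjusted p = 0.0476). The tilt of each library's expression with transcript length also differed with genotype: its correlation across genes ran from -0.384 to -0.00851 in wild type and from 0.0162 to 0.287 in knockout libraries (exact permutation p = 0.00794; genes are not independent replicates). Removing that trend left 97 genes, 70 of them among those called without the removal.

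The 7 week test called 96 of 12002 genes, 54 higher and 42 lower, and DESeq2 called 563 and limma voom 491, each holding all 96. With the oocyte marker level as a covariate 103 passed, 58 of them among the 96. Without the low-depth libraries (wild type 1 and knockout 1) 42 passed and without the 3 shallowest 36, and leaving out single libraries gave 41 without wild type 2, 38 without wild type 3, 36 without wild type 4, 51 without knockout 1, 45 without knockout 3, 43 without knockout 5 and 209 without knockout 4.

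In 6 month granulosa cells the comparison asks what receptor loss changes in mature adults. Thbs4 was 12.2 ± 3.46 CPM (SD, n = 6) in knockout and 242 ± 62.3 (SD, n = 12) in wild type libraries. Its log2 fold change was -4.29 ± 0.24 (edgeR's adjusted p = 1.31e-11). Clu rose from 466.0 ± 199.5 to 2179 ± 407.7 CPM (log2 2.23 ± 0.22), and Fos, an immediate-early transcription factor gene, from 147.9 ± 97.8 to 760.7 ± 340.8 CPM (log2 2.36 ± 0.41). Fshr, the receptor for follicle-stimulating hormone, rose from 11.7 ± 5.81 to 32.8 ± 11.2 CPM (log2 1.499 ± 0.34), and Star from 783.3 ± 357.4 to 1479 ± 296.6 CPM (log2 0.92 ± 0.24). Esr1, the gene of estrogen receptor alpha, was 53.2 ± 37.8 CPM in knockout and 18.4 ± 13.4 in wild type (log2 1.51 ± 0.45, adjusted p = 0.0367, higher in 5 of 6 knockout libraries). The other genes of this paragraph moved in their direction in 6 of 6 knockout libraries.

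Further genes higher in 6 month knockout cells were Grb14 (2.54 ± 0.26), the water channel gene Aqp1 (2.09 ± 0.26), the glutamine synthetase gene Glul (1.73 ± 0.22), Anxa3 (1.63 ± 0.16), the protease-like gene Prss35 (1.48 ± 0.19), Dpysl4 (2.11 ± 0.27), Loxl3 (1.33 ± 0.15), and the neighbours Tmem176a (1.32 ± 0.15) and Tmem176b (1.34 ± 0.15). Lower were the axon guidance gene Sema3a (-2.31 ± 0.32), the lipid kinase gene Pik3cd (-2.31 ± 0.26), Osbpl3 (-2.12 ± 0.30), Arrdc4 (-1.90 ± 0.28), Fhdc1 (-1.36 ± 0.20), Ptprn (-1.34 ± 0.18), the deubiquitinase gene Usp3 (-1.11 ± 0.14) and the arginyltransferase gene Ate1 (-1.07 ± 0.15).

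Immediate-early genes, which also answer to the stress of cell dissociation, were often higher in knockout at 6 months: 8 of 20 were higher and 1 lower over all genes, and 10 and 1 adjusted over the list alone. Dusp1 (2.27 ± 0.30), Nr4a1 (1.94 ± 0.36) and Nr4a2 (1.55 ± 0.32) were among them. Of 26 antioxidant genes, 7 were higher and 1 lower (10 and 2 adjusted over the list alone), including the glutathione transferase gene Gstm1 (1.67 ± 0.33), Nqo1 (1.18 ± 0.30) and Prdx6 (0.77 ± 0.15). Of 24 cholesterol synthesis genes, 4 were higher and none lower (5 adjusted over the list alone), including Fdft1 (1.05 ± 0.28), Insig1 (1.04 ± 0.28) and Dhcr7 (0.90 ± 0.26). Of 19 glycolysis genes, 3 were higher (6 higher and 1 lower adjusted over the list alone), including Aldoc (1.73 ± 0.28) and Ldhb (0.82 ± 0.16). Of 31 chromatin and DNA methylation genes, 8 were lower and 1 higher (11 and 4 adjusted over the list alone): the histone demethylase genes Kdm1a (-0.91 ± 0.22) and Kdm5b (-0.78 ± 0.15) and the methyltransferase gene Ezh2 (-0.73 ± 0.19) were lower, and H1f8, an oocyte linker histone gene, was higher (1.59 ± 0.29). The camera adjusted p was 7.25e-05 for the immediate-early, 0.00732 for the antioxidant, 7.53e-04 for the cholesterol, 0.0157 for the glycolysis and 0.0157 for the chromatin set. None of these 5 set calls held with an estimated correlation (adjusted p = 0.540 with an estimated correlation in each).

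Steroidogenic and luteal genes went both ways at 6 months. Of 16 steroidogenesis genes, 5 were higher and 2 lower, over all genes and over the list alone: Star and Hsd17b7 (0.94 ± 0.22) were higher, and Akr1c18 (-1.38 ± 0.28) was lower, as was Nr5a1 (-0.61 ± 0.12), a transcription factor gene that drives steroid enzyme genes. Of 12 luteal genes, 3 were higher and 3 lower (4 and 3 adjusted over the list alone), among them Sfrp4 (0.97 ± 0.21) and Ptgfr (-2.29 ± 0.46), and Lhcgr had a value of -0.61 ± 0.44 (adjusted p = 0.356). The luteal list's median was 0.20 and its mean -0.13, with a camera adjusted p of 0.788. Of 29 granulosa and FSH-responsive genes, 4 were higher and 3 lower (6 and 4 adjusted over the list alone), with Fst (-1.41 ± 0.25), which binds activin, and Runx2 (-1.11 ± 0.19) lower. Of 32 TGF-beta family genes, 3 were higher and 4 lower (4 and 5 adjusted over the list alone). The receptor genes Tgfbr1 (-1.65 ± 0.26) and Acvr1 (-1.10 ± 0.23) and the effector gene Smad3 (-0.83 ± 0.20) were among the lower ones. Of 28 matrix genes, 5 were higher and 5 lower (9 and 9 adjusted over the list alone), with Nid2 (3.09 ± 0.45) higher and Col5a1 (-1.85 ± 0.36) lower.

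Proliferation, repair and death genes that passed at 6 months were mostly lower. Of 31 cell cycle genes, 5 were lower and 1 higher (6 and 3 adjusted over the list alone), including Mki67 (-0.90 ± 0.25), Top2a (-0.68 ± 0.17), Mcm3 (-0.65 ± 0.20) and the cycle inhibitor gene Cdkn1b (-0.96 ± 0.24). Of 29 DNA repair genes, 4 were lower and 1 higher (5 and 1 adjusted over the list alone): Fancd2 (-1.62 ± 0.43), Brca2 (-1.07 ± 0.28) and Brca1 (-0.97 ± 0.28) were lower and Xrcc6 was higher (0.86 ± 0.23). Of 21 apoptosis genes, 3 were lower (6 lower and 2 higher adjusted over the list alone): the death genes Bcl2l11 (-1.15 ± 0.25) and Apaf1 (-0.997 ± 0.24), and Gadd45a (-0.78 ± 0.26). The camera adjusted p was 0.373, 0.151 and 0.289 for these sets. The cell cycle list's median was 0.02 and its mean -0.08. Of 18 ovulation genes, Cebpb (-2.56 ± 0.65) and pentraxin, Ptx3 (-1.40 ± 0.38), were lower and Adamts1 (0.75 ± 0.21) was higher, and 4 were lower and 1 higher adjusted over the list alone.

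Erythroid markers summed to 56.5 ± 69.2 CPM (SD, n = 6) in 6 month knockout and 363.6 ± 304.8 (SD, n = 12) in wild type granulosa libraries (exact permutation adjusted p = 0.0186). Of 5 erythroid genes 1, Alas2 (-1.63 ± 0.50), was lower over all genes and 5 adjusted over the list alone. Immune markers summed to 782.2 ± 369.6 CPM in knockout and 1946 ± 1777 in wild type, which did not pass (exact permutation adjusted p = 0.382). Of 17 immune genes 3, Cd52 (-1.28 ± 0.33), S100a8 (-5.02 ± 1.48) and S100a9 (-4.72 ± 1.46), were lower, and 9 adjusted over the list alone. Both sets had a camera adjusted p of 0.00286, and adjusted p = 0.540 with an estimated correlation. Oocyte markers were higher in knockout, at 106.3 ± 19.5 against 67.4 ± 14.9 CPM (exact permutation adjusted p = 0.0157).

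At 6 months the test called 1580 of 12505 genes, 824 higher and 756 lower, of which 322 and 241 differed at least 2-fold. With the oocyte marker level as a covariate 882 passed (359 higher, 523 lower), of which 639 were among the 1580. With the erythroid share 290 passed (231 higher, 59 lower), of which 226 were among the 1580. Leaving out knockout 5 gave 926 genes, knockout 2 gave 982 and knockout 3 gave 998.

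Across the 3 ages, 15 genes were higher and 9 lower in knockout granulosa cells at every age, among 11593 tested at all 3. Besides Esr2, those ranked first by the largest of their p included Thbs4, Grb14 and Pak3 (2.12 ± 0.35, 2.13 ± 0.29 and 1.36 ± 0.23 in order of age). So were the muscle and synapse scaffold gene Dtna (2.76, 2.50 and 2.79), the matricellular gene Ccn2 (2.38, 2.60 and 2.09) and Mef2c (1.90, 2.24 and 1.66). Ptgis (2.00, 1.53 and 1.43), Dhrs3 (-1.996, -1.98 and -0.92) and Olfr810 (-3.37, -3.21 and -1.88) belonged to them too. Counting at least 2 ages, 72 genes were higher and 71 lower, and 6 passed in opposite directions at 2 ages. The 4 and 7 week calls shared 24 higher and 21 lower genes, where independent draws would share 0.529 and 0.528. The 4 week and 6 month calls shared 60 and 56 (7.29 and 9.88 by independent draws), with 4 opposite. The 7 week and 6 month calls shared 21 and 14 (3.24 and 2.59), with 2 opposite. Over all genes the Spearman correlation of the log2 fold changes was 0.124, 0.343 and -0.391 for these 3 pairs. Those are correlations across genes, which are not independent replicates.

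**Figure D4:**
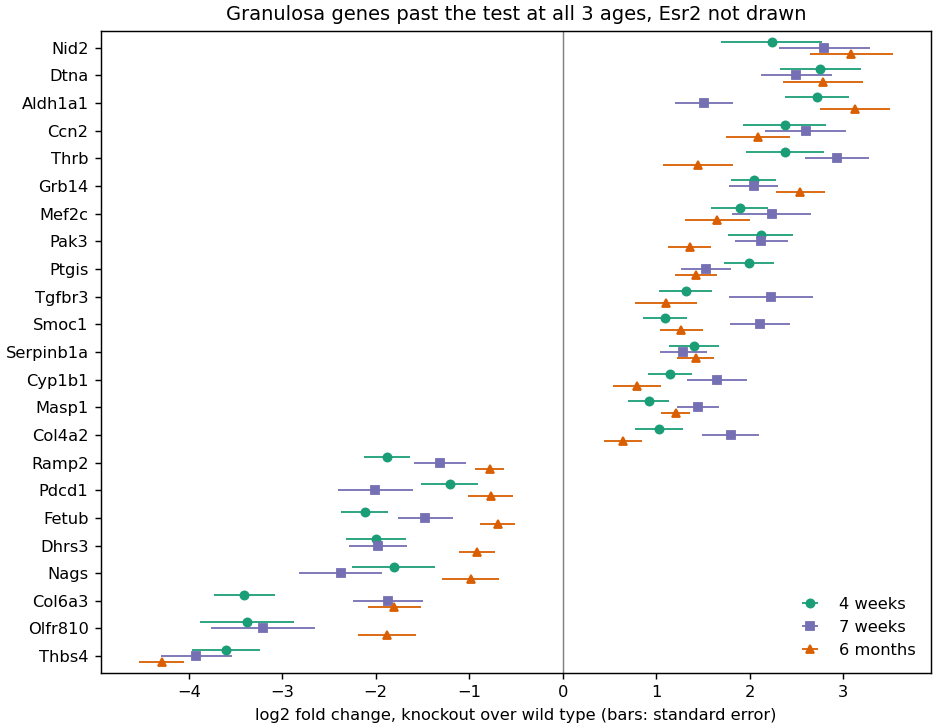
Log2 fold changes (knockout over wild type, x axis) in granulosa libraries of the genes past the test at all 3 ages, with standard errors as bars. Circles are 4 weeks, squares 7 weeks and triangles 6 months, and Esr2 is not drawn. The 15 higher genes lie right of 0 at each age and the lower ones left of 0, with Thbs4 at -3.60, -3.92 and -4.29.

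Tests of the difference between ages, on all granulosa libraries together, asked whether the knockout effect itself changed with age. From 4 weeks to 6 months the effect differed for 94 of 14307 genes, 76 with a higher and 18 with a lower knockout difference at 6 months. Luteal genes led the lists: 3 of 12 had a higher difference at 6 months over all genes and 7 adjusted over the list alone (camera adjusted p = 4.03e-10, and adjusted p = 0.0211 with an estimated correlation). Single genes with a higher difference were Fam20a (3.21 ± 0.46), Slc12a8 (2.64 ± 0.38), Entpd1 (2.37 ± 0.36), Pik3c2g (2.23 ± 0.32) and Col18a1 (1.66 ± 0.27). Those with a lower difference were Thbs1 (-2.44 ± 0.40), Ddit4l (-2.41 ± 0.54), Mreg (-2.29 ± 0.49), the kinase gene Pim1 (-2.10 ± 0.47) and the NF-kappaB gene Rel (-1.72 ± 0.37). From 4 to 7 weeks 1 gene passed, Col18a1 (1.72 ± 0.30, adjusted p = 0.0151), and 1822 had an unadjusted p under 0.05. DESeq2 called 184 genes for the first contrast and 56 for the second, and no gene passed the second with the transcript length trend removed or without 7 week wild type 2, wild type 5, knockout 3 or knockout 4.

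From 7 weeks to 6 months the granulosa knockout effect differed for 1492 genes, 666 higher and 826 lower. With DESeq2's size factors the split was 911 higher and 710 lower. Of 19 glycolysis genes, 6 had a higher difference at 6 months (10 higher and 1 lower adjusted over the list alone), led by Aldoc (3.23 ± 0.61). Of 26 antioxidant genes, 7 did (9 adjusted over the list alone), and of 32 chromatin genes, 9 had a lower and 3 a higher difference (10 and 3 adjusted over the list alone). The camera adjusted p was 2.25e-04, 0.0302 and 0.0295 for these sets, and adjusted p = 0.509 with an estimated correlation in each. Of 11 oocyte markers 6 had a higher difference and of 9 surface epithelium markers 3 (7 and 7 adjusted over the list alone). The camera adjusted p was 0.00348 and 0.00272, and adjusted p = 0.509 with an estimated correlation in each. At 7 weeks oocyte markers summed to 310.9 ± 243.1 CPM in wild type and 89.85 ± 40.54 in knockout granulosa libraries (SD, n = 5 each). Their exact permutation adjusted p was 0.409. Whether oocyte RNA in these libraries enters the values of the oocyte markers was not tested. Rogdi (2.53 ± 0.45), Chchd6 (1.98 ± 0.39), Tmem176b (1.77 ± 0.34) and Ccdc78 (8.59 ± 1.62) had a higher difference, and Pim1 (-2.98 ± 0.53), Rel (-2.40 ± 0.42), Vat1 (-2.35 ± 0.42), Tnpo2 (-2.13 ± 0.37) and the kinesin gene Kif1b (-1.82 ± 0.31) a lower one. With the transcript length trend removed 525 genes passed, 471 of them among the 1492, and DESeq2 called 2343. Leaving out single 7 week libraries gave 290 (wild type 2), 993 (wild type 3), 642 (wild type 4), 897 (knockout 1), 775 (knockout 2), 425 (knockout 3) and 2298 (knockout 4) genes.

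In 4 week oocytes the comparison asks whether receptor loss changes the oocyte itself. Esr2 was the only gene that passed among 10828, and 351 genes had an unadjusted p under 0.05. DESeq2 and limma voom also called 1 gene, Esr2. Of 18 genes of the unfolded protein response and endoplasmic reticulum chaperones none passed, over all genes or over the list alone, and the set's median was -0.23 (camera adjusted p = 0.0233, lower, and adjusted p = 0.0489 with an estimated correlation). Its members Manf, at -0.80 ± 0.25, and Pdia6, at -0.56 ± 0.23, each had an adjusted p of 0.998, with 7 of 7 knockout libraries below the wild type median. Of 34 nuclear-encoded oxidative phosphorylation genes none passed in either count (median -0.29; camera adjusted p = 7.62e-04, lower, but adjusted p = 0.365 with an estimated correlation). Gdf9, a growth factor that the oocyte sends to its granulosa cells, was at -0.39 ± 0.26, and Esr1 at 0.12 ± 0.18 (adjusted p = 0.998 each).

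In 7 week oocytes 18 of 11711 genes passed, 2 higher and 16 lower in knockout. The higher ones were Septin12, a cytoskeletal septin gene, at 15.5 ± 6.85 CPM (SD, n = 12) against 3.94 ± 1.82 (SD, n = 5; log2 1.94 ± 0.37), and Ptar1 (1.28 ± 0.25), each in 12 of 12 libraries. Lower, besides Esr2, was Cyp11a1, at 1.80 ± 1.88 against 32.1 ± 21.8 CPM (log2 -4.14 ± 0.61). Further lower genes were Tmem86a (-4.46 ± 0.68), the aldo-keto reductase gene Akr1cl (-1.90 ± 0.31), Chchd10 (-2.90 ± 0.50), the nuclear RNA gene Malat1 (-2.90 ± 0.53), Tceal9 (-3.13 ± 0.60), Bspry (-2.22 ± 0.43), the ferritin gene Fth1 (-2.22 ± 0.43) and Cript, at 27.6 ± 5.31 against 62.0 ± 31.8 CPM (-1.17 ± 0.23). The sample numbers were taken as pairs at this age, which the labels do not state. Knockouts 1 and 5 correlated best with the wild type library of their own number, and knockouts 2 and 3 with another. With the number as a block, over the 8 libraries of 4 pairs, 10 of the 18 passed and 2, Krt18 among them, were not tested. The other 6 did not pass, among them Chchd10 (-1.93 ± 0.53, adjusted p = 0.107), Septin12 (1.57 ± 0.48, adjusted p = 0.142), Bspry (-1.46 ± 0.53, adjusted p = 0.216), Cript (-0.69 ± 0.25, adjusted p = 0.211) and Ptar1 (1.17 ± 0.39, adjusted p = 0.180). Wild type granulosa libraries of that age held Cyp11a1 at 5713 CPM and Akr1cl at 7468 CPM. Transcripts abundant in granulosa cells were higher in the wild type than in the knockout oocyte libraries, at 1.16% ± 0.896 (SD, n = 5) against 0.271% ± 0.169 (SD, n = 12) of their granulosa level (exact permutation p = 0.00598, without pairing; lower in knockout in 3 of 4 pairs). Endothelial markers summed to 119 ± 23.2 CPM in knockout and 83.3 ± 10.6 in wild type (exact permutation adjusted p = 0.0157, without pairing; higher in knockout in 4 of 4 pairs). Oocyte markers summed to 45430 ± 7963 CPM in knockout and 32980 ± 9488 in wild type (exact permutation p = 0.0181, adjusted p = 0.0921, without pairing; higher in knockout in 4 of 4 pairs). Surface epithelium markers, of which Krt18 is 1, summed to 15.23 ± 4.597 CPM in knockout and 44.74 ± 52.59 in wild type (exact permutation p = 0.0212, adjusted p = 0.0953, without pairing; lower in knockout in 4 of 4 pairs). A permutation within 4 pairs gives no p under 0.125.

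No oocyte gene group gave a passing member at 7 weeks except through Esr2, Cyp11a1 and Krt18. Of 23 zona pellucida and oocyte-secreted genes none passed in either count (median 0.32, camera adjusted p = 0.00156, higher, but adjusted p = 0.313 with an estimated correlation). Gdf9 was 15650 ± 5172 CPM (SD, n = 12) in knockout and 8705 ± 3215 (SD, n = 5) in wild type. Its log2 value was 0.85 ± 0.28 (adjusted p = 0.179, above the wild type median in 10 of 12 libraries), and Mos, a kinase gene of meiotic arrest, had a value of 0.93 ± 0.28 (adjusted p = 0.152). Of 29 cytosolic ribosomal protein genes none passed over all genes and 2 were lower adjusted over the list alone (median -0.63, camera adjusted p = 2.51e-05, but adjusted p = 0.278 with an estimated correlation). Of 36 oxidative phosphorylation genes none passed over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 0.00156, but adjusted p = 0.272 with an estimated correlation and adjusted p = 0.456 with the number as a block). Of 7 luteal genes 1, Cyp11a1, was lower over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00156, but adjusted p = 0.272 with an estimated correlation). Akr1c18 had a value of -3.996 ± 0.86 (adjusted p = 0.0567).

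The 7 week oocyte count moved with most choices. With the sample number as a block 38 genes passed (16 higher, 22 lower), 10 of them among the 18, while DESeq2 called 238, limma voom 117, and limma on the authors' normalised values 1. With the granulosa marker level as a covariate 1 gene passed, Esr2. Without single wild type libraries 7 (wild type 1), 2 (wild type 2), 61 (wild type 3), 8 (wild type 4) and 9 (wild type 5) genes passed. Without single knockout libraries 296 (knockout 1), 28 (knockout 2), 7 (knockout 8), 6 (knockout 10) and 5 (each of knockouts 3, 5, 6, 7, 11 and 12) passed. Without the unnumbered knockout library 17 passed, all among the 18.

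In 6 month oocytes Esr2 was again the only gene to pass, among 12225, and 396 had an unadjusted p under 0.05. DESeq2 and limma voom also called 1. Of 32 cytosolic ribosomal protein genes none passed in either count (median -0.69, camera adjusted p = 2.01e-09, lower, but adjusted p = 0.283 with an estimated correlation), and of 36 oxidative phosphorylation genes none did (median -0.33, camera adjusted p = 5.67e-05, lower, but adjusted p = 0.283 with an estimated correlation). Rps14 had a value of -0.84 ± 0.27 and Atp5j of -1.56 ± 0.63 (adjusted p = 0.999 each). Gdf9 (0.24 ± 0.31), Zp3 (-0.17 ± 0.23) and Esr1 (-0.02 ± 0.31) did not pass either. The oocyte knockout effect did not differ between ages for any of 13471 genes. Genes with an unadjusted p under 0.05 numbered 1526 (7 weeks against 4 weeks), 397 (6 months against 4 weeks) and 409 (6 months against 7 weeks), and DESeq2 called 12, 0 and 0. On simulated counts a 2-fold difference between ages was recovered for 11.1% (7 weeks against 4 weeks) and 6.06% (6 months against 7 weeks) of genes and a 4-fold one for 49.5% and 43.3%, so real differences can have been missed. Esr2, the mutated gene, was the only gene lower in both cell types at 4 weeks and at 6 months. At 7 weeks 2 lower genes were shared, Esr2 and Krt18. Independent draws would share 0.0344, but Esr2 is shared by design, so the comparison tests nothing. Krt18 is a surface epithelium marker. Those markers, Krt18 included, summed lower in knockout in both cell types (exact permutation adjusted p = 0.0476 in granulosa and 0.0953 in oocytes). The oocyte sum did not pass. Neither sum was computed without Krt18, so the sums are no separate support for it. On simulated counts at these group sizes a 4-fold change was recovered for 95.8%, 80.0% and 70.1% of genes in oocytes at 4 weeks, 7 weeks and 6 months, and a 2-fold change for 41.2%, 33.3% and 21.0%.

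Wild type libraries of different ages show how libraries without the mutation differ between ages. Each age came in its own table, so age cannot be told apart from any difference in preparation or sequencing between tables. In each cell type the same 5 wild type libraries of 7 weeks entered both age contrasts and the 7 week knockout comparison. A shift of those libraries alone would thus enter each of these results. In wild type granulosa cells no gene passed between 4 and 7 weeks (1357 with an unadjusted p under 0.05, and 1 by DESeq2). From 7 weeks to 6 months 194 passed, 35 higher and 159 lower. Hif1a, the hypoxia-response transcription factor gene, was higher (1.30 ± 0.23), as were Uck2 (1.22 ± 0.25), the cell cycle genes E2f2 (1.41 ± 0.29) and Prc1 (0.83 ± 0.18), and Lpgat1 (1.38 ± 0.29). Esr2 itself was lower (-1.11 ± 0.29, adjusted p = 0.0462), as was the steroid enzyme gene Hsd3b1 (-1.19 ± 0.23). Of 24 cholesterol synthesis genes, 2 were higher over all genes and 19 adjusted over the list alone, such as Mvd (1.37 ± 0.35) and Cyp51 (1.33 ± 0.34). The camera adjusted p of that set was 8.28e-17, and adjusted p = 0.102 with an estimated correlation. Oocyte genes were among the lower ones, with 8 of 11 oocyte markers (10 adjusted over the list alone) and 12 of 20 maternal-effect genes (14 adjusted over the list alone), among them Dazl (-4.04 ± 0.68), Bmp15 (-3.64 ± 0.68), Bcl2l10 (-2.96 ± 0.48), AU022751 (-3.86 ± 0.62), C86187 (-3.67 ± 0.62) and C87499 (-4.31 ± 0.72). Oocyte markers summed to 310.9 ± 243.1 CPM (SD, n = 5) in 7 week and 67.4 ± 14.9 (SD, n = 12) in 6 month wild type granulosa libraries. The 7 week libraries ran from 38.42 to 527.1 CPM. The values of these oocyte genes are thus not clearly ones of granulosa cells, and oocyte RNA as their source was not tested. The set of oocyte markers had a camera adjusted p of 2.76e-10, and adjusted p = 0.102 with an estimated correlation. DESeq2 called 364 genes, a mean of at least 10 CPM left 120, and without the low-depth libraries 309 passed; without 7 week wild type 1 the count was 333, without wild type 3 it was 86 and without wild type 4 it was 82.

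In wild type oocytes 111 of 13471 genes passed between 4 and 7 weeks, 33 higher and 78 lower, and 3100 had an unadjusted p under 0.05. Among the lower were the chaperone genes Hspa5 (-0.90 ± 0.20) and Pdia6 (-0.998 ± 0.24), Gdf9 (-1.22 ± 0.31) and the zona pellucida gene Zp1 (-1.21 ± 0.32). Of 23 zona pellucida and oocyte-secreted genes 2 were lower over all genes and 9 adjusted over the list alone (camera adjusted p = 2.04e-04, and adjusted p = 0.263 with an estimated correlation). Oocyte markers summed to 49580 ± 7937 CPM (SD, n = 12), 32980 ± 9488 (n = 5) and 56370 ± 11540 (n = 11) in wild type oocytes, in order of age. Knockout oocytes of 7 weeks held 45430 ± 7963 (n = 12). Whether age or a shift of the 7 week wild type libraries alone sets these genes apart was not tested. Lurap1l (-1.61 ± 0.30), Lamtor1 (-1.32 ± 0.28), Bscl2 (-0.99 ± 0.21), Senp5 (-0.84 ± 0.17) and Rnf216 (-0.75 ± 0.16) were lower, and Cyp11a1 (3.39 ± 0.76), Dtx3l (1.77 ± 0.41), Smarcc2 (1.55 ± 0.31), Epb41l4b (1.06 ± 0.24) and Elk4 (1.01 ± 0.21) higher. Cyp11a1 is abundant in granulosa cells, and the 7 week wild type oocyte libraries held granulosa transcripts at 1.16% of their granulosa level, so its value is not clearly one of oocytes. The count of passing genes was 1115 by DESeq2 and 542 at a mean of at least 10 CPM, and it was 0 without 7 week wild type 1 or wild type 2, 4 without wild type 4, 520 without wild type 5, and 12 and 16 without 6 month knockout 1 and knockout 2, which are outside the contrast but enter its fit and gene filter.

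Between 7 weeks and 6 months 3463 wild type oocyte genes passed, 1767 higher and 1696 lower, of which 1870 differed at least 2-fold. Of the zona pellucida and oocyte-secreted genes 14 of 23 were higher and 1 lower, over all genes and over the list alone, such as Zp3 (1.82 ± 0.27), the sperm-binding zona protein gene, and Oosp1 (1.31 ± 0.22). The camera adjusted p was 2.07e-05, and adjusted p = 0.209 with an estimated correlation. Of 33 chromatin genes, 13 were lower and 4 higher (13 and 5 adjusted over the list alone), with Kmt2d (-1.70 ± 0.22) and the DNA demethylase gene Tet3 (-1.30 ± 0.21) lower and the histone acetyltransferase gene Hat1 (1.27 ± 0.23) higher (camera adjusted p = 0.0168, and adjusted p = 0.228 with an estimated correlation). Of 40 meiosis genes, 11 were higher and 5 lower (15 and 5 adjusted over the list alone), with the spindle checkpoint gene Bub3 (1.75 ± 0.24) and Aurkb (1.83 ± 0.41) among the higher. Of 37 oxidative phosphorylation genes, 8 were higher and 1 lower over all genes and over the list alone, such as Ndufa4 (2.53 ± 0.41). The smallest p belonged to the proteasome gene Psma2 (1.76 ± 0.21), the histone gene H3f3a (2.14 ± 0.27), the ubiquitin-conjugating genes Ube2c (2.00 ± 0.26) and Ube2t (2.29 ± 0.30) and Tcstv1 (2.02 ± 0.26), all higher, and to Hectd4 (-1.88 ± 0.21), the chromatin remodeller gene Srcap (-2.55 ± 0.29), Tnrc6b (-1.76 ± 0.22) and Pptc7 (-1.35 ± 0.18), all lower. Without 7 week wild type 1 the count was 1933. With the transcript length trend removed 2458 genes passed, 2022 of them among the 3463.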

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

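The tests of transcript length below were chosen only after the result was seen, as was the use of the planned set without low-depth libraries as a test; the tests of single libraries and of differences between ages were planned.

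Of 66 combinations of a measure and a group of 4 to 10 libraries tested, 7 held a library far from the others (granulosa 4 week knockout 1 in 2 of them), and chance gives about 1 in 20. Granulosa 4 week wild type 4 had a total of 6.469 M counts (M for mega), against 1.414 to 3.594 M in the others. Genes detected numbered 14087 in granulosa 7 week wild type 1 (others 16814 to 17832) and 13173 in oocyte 7 week wild type 1 (others 14523 to 14907). Granulosa 4 week knockout 1 had 40.88 CPM of erythroid markers (others 9.233 to 22.4) and Akr1c18 at 562.99 CPM (others 147.42 to 268.77). Granulosa 7 week knockout 1 had 159.6 CPM of oocyte markers (others 54.98 to 83.42), and granulosa 6 month knockout 6 had Thbs4 at 5.4658 CPM (others 12.37 to 15.212).

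The granulosa knockout effect differed between ages by a test of the difference itself for 1 gene (7 weeks against 4 weeks), 94 genes (6 months against 4 weeks) and 1492 genes (6 months against 7 weeks). In the first contrast the gene was Col18a1 (log2 1.72). In the next, Slc12a8 (2.64), Fam20a (3.21), Pik3c2g (2.23), Entpd1 (2.37) and Col18a1 (1.66) had a higher difference at 6 months, and Thbs1 (-2.44), Mreg (-2.29), Rel (-1.72), Pim1 (-2.10) and Ddit4l (-2.41) a lower one. In the last, Rogdi (2.53), Ccdc78 (8.59), Aldoc (3.23), Tmem176b (1.77) and Chchd6 (1.98) had a higher difference, and Kif1b (-1.82), Rel (-2.40), Tnpo2 (-2.13), Pim1 (-2.98) and Vat1 (-2.35) a lower one.

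The 1492 genes between 7 weeks and 6 months were weighed against transcript length and depth. Shallow libraries as the whole cause are argued against by the 977 genes (65.5%) still called without the low-depth ones. A length trend as the whole cause is argued against by the 471 genes (31.6%) that were still called with it removed. Their median difference was 1.79 before and 1.64 after (median SE 0.454 and 0.446). This covers only the trend as removed, on each gene's longest annotated transcript, and a trend left after removal was not tested. The other 1021 calls ended, with a median difference of 1.31 before and 0.92 after (median SE 0.393 and 0.345), and all 1021 kept their sign. They ended with smaller differences and not with larger errors on the median, but choosing genes for losing the call brings some of that shrinkage itself. For these a length trend may be the cause and cannot be told apart from the mutation, since the length correlation of the 7 week libraries itself differs with genotype (exact permutation p = 0.00794; at 6 months p = 0.0552). An effect of age on the knockout stays open, as untested, and so does any difference between the tables of the 2 ages.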

How the results depend on the processing

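Of these settings, the trend removals, the erythroid and immune covariates, the lists without Esr2 and the set without the 3 shallowest libraries were chosen only after the data were seen. The cause of each change below was not tested, except that fewer genes entered the stricter filter and more the filter-free set, and fewer libraries the left-out sets and the replicate block. With the DESeq2 test the counts were 559 and 563 (granulosa 4 and 7 weeks), 238 (oocytes 7 weeks), 56, 184 and 2343 (granulosa knockout effect, 7 weeks against 4, 6 months against 4 weeks, 6 months against 7 weeks), 12 (oocyte knockout effect, 7 weeks against 4), 1 and 364 (granulosa wild type, 7 weeks against 4, 6 months against 7 weeks) and 1115 (oocyte wild type, 7 weeks against 4). With limma voom they were 446 and 491 in granulosa and 117 in oocytes at 7 weeks, and with limma on normalised values 1 in those oocytes. The replicate block gave 645 in granulosa at 6 months and 38 in oocytes at 7 weeks. The other cell type's markers as a covariate gave 882 and 1 for the same comparisons. The erythroid share gave 22 (4 weeks) and 290 (6 months) and the immune share 90 (4 weeks) in granulosa. Without low-depth libraries 42 passed in granulosa at 7 weeks and 309 in granulosa wild type from 7 weeks to 6 months, and without the 3 shallowest 36 at 7 weeks. In oocytes at 7 weeks 30 passed with no filter and 11 at a mean of at least 10 CPM, which gave 120 in granulosa wild type from 7 weeks to 6 months and 542 in oocyte wild type from 4 to 7 weeks. With the length trend removed the granulosa knockout effect gave 0 (7 weeks against 4) and 525 (6 months against 7 weeks), and with length and GC 0 and 584, with 301 in granulosa wild type from 7 weeks to 6 months and 176 in oocyte wild type from 4 to 7 weeks.

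Leaving out each library gave 213 to 303, 36 to 209 and 926 to 2057 genes in granulosa (4 weeks, 7 weeks, 6 months) and 1 to 1, 2 to 296 and 1 to 1 in oocytes. For contrasts between ages only the 10 granulosa libraries of 7 weeks, and the 9 oocyte libraries of 7 week wild type and 6 month knockout, were left out in turn. The granulosa knockout effect gave 0 to 1 (7 weeks against 4), 79 to 97 (6 months against 4 weeks, where no library of either age was left out, so the range does not show how stable the count is) and 290 to 2298 (6 months against 7 weeks). That of oocytes gave 0 to 0 in each contrast, wild type granulosa 0 to 0 and 82 to 333, and wild type oocytes 0 to 520 and 1933 to 3506.

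The direction turned for Hbb-bs with the erythroid covariate (0.38) and Lyz2 with the immune covariate (0.0563) at 4 weeks, and without Esr2 for the steroid receptor list in oocytes (adjusted p = 0.421 at 4 weeks, 0.608 at 7 weeks, 0.615 at 6 months) and the list of genes near Esr2 in 4 week oocytes (0.992). Over the settings other than leaving out single libraries, named genes kept direction and side of the threshold in 5250 values, ended in 419, newly passed in 21 and turned in 2; lists did so in 496, 50, 16 and 4. Without single libraries named genes kept both in 6793 values, ended in 493 and newly passed in 20. Low-depth sets had no value where no library was shallow. Besides the genes and the list named with it, the replicate block changed none of the calls given for 7 week oocytes. The 7 week granulosa comparison held the shallowest library and the fewest libraries, 10, and a simulated 2-fold change was recovered for 13.7% of genes there; what depth alone limits was not separated from group size.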

Other observations

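The tests of RNA from other cells below were chosen only after the result was seen; the splits of the samples were planned.

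Several gene groups not described so far differed in 6 month granulosa cells. Of 26 genes of maternal mRNA storage and translation control, 5 were lower in knockout over all genes (9 lower and 3 higher adjusted over the list alone), among them Lsm14b (-1.34 ± 0.34 SE), Mettl14 (-0.99 ± 0.26) and the uridyltransferase genes Tut4 (-0.81 ± 0.25) and Tut7 (-0.79 ± 0.18). Of 28 meiosis and spindle genes 4 were lower, in both counts, among them Kif11 (-0.83 ± 0.21) and Tpx2 (-0.66 ± 0.18), which also serve mitosis. Of 8 surface epithelium markers, Msln (2.46 ± 0.76) and Upk1b (1.58 ± 0.46) were higher, with 4 higher adjusted over the list alone. Of 20 endoplasmic reticulum chaperone genes Hspa5 was higher (0.67 ± 0.18) and Edem1 lower (-0.80 ± 0.19), in both counts.

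The 15 genes besides Esr2 that were lower in 7 week knockout oocytes were weighed against granulosa RNA in the wild type libraries. Over 173 transcripts abundant in granulosa cells, wild type oocytes held 1.16% and knockout oocytes 0.271% of the granulosa level (exact permutation p = 0.00598, from 0.000549 to 0.0275 without single wild type libraries, the last without wild type 2). Spp1 was at 34490 CPM in granulosa, 284.6 in wild type and 25.8 in knockout oocyte libraries, and Ephx2 at 7588, 78.0 and 12.2. Such RNA may account for 10 of the 15, whose excess lay within that of the central 95% of those transcripts (0.0373% to 3.26%), but not for Bspry (102% ± 26.3 SE) and Cript (31.5% ± 12.3), since the smaller of their excesses less 2 SE was 6.98%, and Malat1, Gm37376 and Krt18 stay open (Krt18 is a surface epithelium marker, and RNA of that epithelium was not tested as a source). Bspry and Cript did not pass with the sample number as a block (adjusted p = 0.216 and 0.211). The fixed granulosa markers showed no such difference. They summed to 913.1 ± 153.9 CPM (SD) in knockout and 848.5 ± 293.4 in wild type, with 11 of 12 knockout libraries above the wild type median (exact permutation p = 0.393). These markers were at 13210 CPM in wild type granulosa libraries of that age. The difference between 1.16% and 0.271% of that is below the SD of either oocyte sum (153.9 and 293.4 CPM). The marker sum, though its mean was higher in knockout, can therefore not decide on such RNA. In addition, 17 of the 173 transcripts had at least 5 CPM in knockout oocytes, 8 called genes were taken off the list before the test, and a change inside the oocyte was not tested.

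The lower luteal genes of 4 week knockout granulosa cells were weighed against other cells. Blood and immune RNA in wild type libraries as the whole cause is argued against by the luteal list's camera p with an estimated correlation, at most 0.00222 with either share as a covariate (0.000597 with the immune share, 0.000491 with none). Theca and stroma RNA, with markers lower in knockout too, as the whole cause is argued against by p = 0.00485 with their share as a covariate. That share rested on Apoe: without it the other 14 markers summed to 262.8 ± 49.6 CPM (SD) in knockout and 289.9 ± 157.8 in wild type (exact permutation p = 0.951). The list's median went from -0.99 to -1.06 with the erythroid share, -1.27 with the immune share and -0.96 with the theca and stroma share. Fewer mural cells in knockout libraries could also lower these genes and cannot be told apart from a change inside the cells. The 3 mural markers outside the luteal and ovulation lists summed to 26.4 CPM in knockout and 14.1 in wild type (exact permutation p = 0.0105). They lie near the floor, and Cyp19a1 among them had a negative log2 value that did not pass.

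Other splits of the libraries, 100 drawn for each result with the real one included, show how often a redrawn grouping calls as many genes. They judge the number of calls and no single gene, and they treat each library as a replicate. For granulosa knockout against wild type few did. At 4 weeks 2 splits called at least the real 283 genes (highest other 749), and at 7 weeks 4 called at least 96 (1475). At 6 months 1 called at least 1580, the real one (highest other 79). The splits with 749 and 1475 genes, several times the real counts, point to a structure of the libraries other than genotype, which was not looked into. In oocytes 4 splits reached the real 1 at 4 weeks (highest other 4) and 10 at 6 months (highest other 542, again several times the real count). At 7 weeks 2 reached 18 (highest other 73). A count of 1 does not test its gene, Esr2, and tells nothing of any other gene. At 6 months Esr2 had 0 counts in 4 of 4 knockout and 87 to 590 in 11 of 11 wild type libraries. Among 50 splits that part as many 7 week oocyte pairs, 1 reached 18, the real one (highest other 3). For the granulosa knockout effect only the real grouping reached 94 between 4 weeks and 6 months (highest other 37). Only the real one reached 1492 between 7 weeks and 6 months (highest other 138). Between 4 and 7 weeks 10 splits reached the real 1 (highest other 473). In wild type granulosa between 7 weeks and 6 months only the real grouping reached 194 (highest other 60). In wild type oocytes only the real one reached 111 between 4 and 7 weeks (highest other 20). Between 7 weeks and 6 months only the real one reached 3463, though another called 2732. Where the real count was 0 all 100 reached it: granulosa wild type from 4 to 7 weeks (highest other 187) and the oocyte knockout effect (7, 45 and 151).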
